A study of Scleronephthya gracillimum with 13 samples.

How the data were processed

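RNA of pooled polyps of Scleronephthya gracillimum was hybridised to 13 Agilent custom arrays with 2 colours, Cy3 for the control and Cy5 for the treated polyps per the labels, with no dye swap. Scanner files, tables of ratios and a matrix of values were available for every array. The spot and local background intensity values are scanner medians, not normalized, per the file headers, which name Agilent Feature Extraction 10.7.3.1 for the heat and acidification arrays and 11.5.1.1 for the combined arrays. The submitters' processing notes name version 9.3.2.1. The scanner log10 ratio was background-subtracted and dye-normalized by the Feature Extraction software, per the file headers. The tables hold a ratio of treated over control signal that the authors had dye-normalized. The deposited matrix holds log10 of that ratio: it differed from log10 of the tables' ratio by at most 5e-10, so scale and direction are known. Its lowest value was -2 on most arrays, and its array medians lay between -0.0202 and 0.0416. The probes that the authors listed as reliable were those well above background in both channels.

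From the scanner files, the median spot signal was corrected for background with normexp (offset 50) in limma 3.58.1 under R 4.3.3 and normalized within each array by loess, with control spots at weight 0. The ratios were not normalized between arrays. Control spots and outlier spots were left out, and each probe had 1 spot. Of 33828 probes on the array, 33760 had an annotation and 27793 were kept, being well above background in at least 1 channel on at least 2 of the 13 arrays. Different probes of a gene were kept apart and counted as probes. Between 59.4% and 73.3% of probes were well above background in the treated channel and between 61.1% and 70.8% in the control channel. Descriptions came from the deposited tables, and 12134 probes had an informative one. They name similar genes of other species, and a few best matches, to microbial genomes or clones, name no gene.

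Log2 ratios of all 13 arrays were fitted with limma's lmFit and eBayes, with 1 coefficient each for 26 °C, 28 °C, acidification and the 3 combined treatments, which share one estimate of the spread (7 residual degrees of freedom, 1.88 prior degrees of freedom). Tests were two-sided. Ratios against 0 test each treatment against the control RNA on the same arrays. These tests leave out the control's own spread. They cannot separate a probe dye bias, since no dye was swapped. Differences between treatments cancel such a bias. P-values were adjusted by Benjamini-Hochberg over the kept probes with a threshold of 0.05. A fit of this kind assumes that a treatment left with 1 array varies like the others. A probe that was well above background on no array of a treatment in 1 channel, but on some in the other, has only a bound there. It is given as "at least N-fold": the mean log2 signal of the bright channel, from intensities normalized between arrays for this purpose (Aquantile in limma), against the mean, per array, of the higher of the dim probe's signal and the lowest signal of probes well above background. Such bounds are open to dye bias.

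Gene lists were fixed as text patterns before the data were examined, as were the design, the alternatives and the rule for named genes. The lists were tested with limma's camera, with a preset inter-gene correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison. A list needed 5 kept probes. The rule named, per comparison, up to 6 annotated probes with the largest change in each direction that passed and moved the same way on every array, 1 per description, and the passing member of each list with the smallest p in each direction. It also named the brightest probe of HSP70, HSP90, alpha crystallin, DnaJ, calreticulin, superoxide dismutase, catalase, peroxiredoxin, ferritin and carbonic anhydrase, and where none passed the 3 annotated probes of smallest p. No peroxiredoxin probe was kept. The text gives a selection of the genes so named.

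The fit was tested on simulated data, with 100 of 27793 probes changed by 1 log2 unit and 100 by 2 in each comparison against a control. For acidification it recovered 37% and 71% of them with 6 false calls, for 28 °C 22% and 58% with 3, and for 28 °C with pH 7.0 22% and 73% with 11. The simulated noise was independent between arrays, whereas real arrays of a slide carried nearly identical control signals. False calls from a deviation shared by the arrays of a slide were therefore not measured.

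The replicate numbers in the labels were checked for pairing. Differences between replicates correlated across probes by 0.603, 0.393 and 0.666 between the 3 combined treatments, whose replicate 1 arrays lay on one slide and replicate 2 arrays on another, so there the number is the slide. In the heat experiment the correlation was -0.266, and there replicate 1 at 26 °C shared a slide with replicate 2 at 28 °C, and the reverse. The titles of the authors' tables name 24 h for the combined arrays of replicate 1 and 48 h for those of replicate 2, while the labels give 24 h for both. All acidification arrays lay on 1 slide, so slide and treatment cannot be told apart there.

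Alternatives were the scanner software's log ratio, median centring, scaling between arrays, no background correction, the matrix values, other filters on dim probes, array weights, the spread of the arrays compared alone, the replicate number or the slide as a block, and leaving out each array. Median centring moved the median of all probes on an array by up to 0.283 on the log2 scale, as on replicate 2 at pH 7.8, so changes are given relative to each array's loess curve. The 68 probes without an annotation were not analysed here. Figures were drawn with matplotlib 3.10.9.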

Results

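Gene expression was measured in polyps of the soft coral Scleronephthya gracillimum, an octocoral that lives without symbiotic algae, after exposure to warm water, acidified water or both. Each of the 13 arrays compared RNA of treated polyps, labelled with Cy5, with RNA of control polyps, labelled with Cy3. There were 2 arrays at 26 °C and 2 at 28 °C against a control at 24 °C, and 1 array each at pH 6.5, pH 7.0 and pH 7.5 against a control at pH 8.0. There were 2 arrays each at 28 °C with pH 7.0, pH 7.5 or pH 7.8, against a control at 24 °C and pH 8.0. The labels give an exposure of 24 h, and the design text gives 3 individual corals per group, with RNA pooled from polyps. The median signal was 1.92 to 4.09 times the background in the treated channel and 2.46 to 4.13 times in the control channel. The number of arrays limits the precision, and the p-values measure the spread between arrays of pooled RNA. In acidification that spread includes the differences between pH 6.5, pH 7.0 and pH 7.5, which were fitted as 1 treatment. All comparisons share this estimate of the spread.

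Genes are named as the deposited annotation describes each assembled sequence (contig), and 1 description can cover many contigs. The description "snRNA-associated Sm-like protein" stood on 522 of the 27793 kept probes, "TNF receptor-associated factor" on 91 and "Transcription factor PAX1/9" on 18. All values are log2 ratios of treated over control, with the standard error of limma's fit.

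The first comparison asked how polyps at 26 °C differed from those at 24 °C. Genes of energy supply and protein turnover lay slightly above the other probes. Of 93 probes of the mitochondrial respiratory chain, 66 had ratios above 0, with a median log2 ratio of 0.10. Of 29 probes of the HSP70 family, chaperones that refold damaged proteins, 23 were above 0, with a median of 0.18. The median was 0.09 for 355 probes of the proteasome and ubiquitin system, 0.11 for 61 probes of glycolysis and the citric acid cycle, and 0.08 for 169 probes of translation factors and tRNA synthetases. With camera and a preset correlation, the adjusted p was 0.0106 for the respiratory chain, for HSP70 and for the proteasome, 0.0117 for glycolysis and 0.0186 for translation. With an estimated correlation the adjusted p was 0.451, 0.513, 0.451, 0.451 and 0.564 in that order, so none of the 5 lists passed. The calls rested on 1 array: without replicate 2, the adjusted p with the preset correlation was 0.966 for the respiratory chain, 0.888 for HSP70, 0.888 for the proteasome, 0.507 for glycolysis and 0.966 for translation, with medians of -0.0308, 0.015, 0.029, 0.0392 and 0.0197. The sizes also depended on the normalization: under median centring the medians were 0.51, 0.51, 0.36, 0.62 and 0.44.

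No single probe passed at 26 °C: limma gave 0 probes at an adjusted p under 0.05 and 1122 (4.04%) at an unadjusted p under 0.05. The annotated probes of smallest p were those of the alpha subunit of mitochondrial processing peptidase (contig10269, at least 2.44-fold higher, adjusted p = 0.409), of an Sm-like protein (contig24939, log2 -2.34, adjusted p = 0.498) and of a glutathione S-transferase (contig15720, log2 2.26, adjusted p = 0.692). The control channel of the peptidase probe was not well above background on either array, and the probe was higher on all 13 arrays of the study. Adjusted over the list alone, 1 probe each of the antioxidant and replication lists was higher. With the scanner software's dye normalization contig10269 passed (adjusted p = 0.0163). Without replicate 2, 11 probes passed, and without replicate 1, 1 passed.

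At 28 °C against 24 °C, 80 of 100 probes of DNA replication, the cell cycle and histones had ratios above 0, with a median of 0.65 that came from replicate 2 (1.23, against 0.02 in replicate 1). The 84 probes of other heat shock proteins and cytosolic chaperones had a median of 0.19, and the 29 HSP70 probes a median of 0.22, with 23 above 0. None of these passed over all probes, while 4 HSP70 probes were higher when adjusted over the list alone. Probes of the extracellular and skeletal matrix lay lower, with 163 of 232 below 0 and a median of -0.16. The brightest HSP70 probe (contig06813) had a log2 ratio of 1.18 (SE 0.339, 2 arrays, adjusted p = 0.392). The alpha crystallin probe (contig05676), of the small heat shock proteins, had 0.89 (adjusted p = 0.392), HSP90 (contig19522) 0.49 (adjusted p = 0.422) and calreticulin (contig02102), a calcium-binding chaperone of the endoplasmic reticulum, 0.89 (adjusted p = 0.399).

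With camera and the preset correlation, the adjusted p was 1.72e-08 for replication, 0.00146 for the matrix, 0.00425 for the other heat shock proteins and 0.00932 for HSP70, and with an estimated correlation it was 0.351 for all 4. With the preset correlation it was also 0.00932 for DNA repair (median 0.27) and for the list fixed as photosynthesis and algal markers (median 0.35), and 0.0356 for the respiratory chain (median 0.09), the proteasome (median 0.10) and actin, tubulin and muscle (median -0.06, which turned to 0.01 under median centring). With an estimated correlation these had 0.43 for DNA repair and for actin and 0.351 for the others. The members of the algal list on the array were largely ribosomal proteins described as of mitochondria or chloroplasts, which an animal also has. Without replicate 2 the adjusted p of the replication list was 0.471. The calls of DNA repair (0.721), the matrix (0.0766), the algal list (0.342) and actin (0.721) also ended without replicate 2, with medians of -0.0087, -0.0591, 0.0586 and 0.0153. The calls of HSP70 (0.262), the other heat shock proteins (0.118), the respiratory chain (0.475) and the proteasome (0.277) ended without replicate 1. Under median centring the median was 0.998 for replication, 0.51 for DNA repair, 0.67 for the algal list, 0.62 for the other heat shock proteins, 0.49 for HSP70, 0.39 for the proteasome, 0.18 for the respiratory chain and -0.03 for the matrix. The respiratory chain had 0.0716, the proteasome 0.0688 and actin 0.0946 with the scanner software's normalization.

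Replicate 2 at 28 °C stood apart from the other heat arrays: 4495 probes were at least 2-fold higher and 3850 at least 2-fold lower, against 279 and 372 in replicate 1. No probe passed at 28 °C with limma, and 3476 (12.5%) had an unadjusted p under 0.05. The smallest p values among annotated probes were those of the peptidase (contig10269, at least 2.6-fold higher, adjusted p = 0.149), a von Willebrand factor-like protein (contig08140, log2 -3.48, SE 0.394, adjusted p = 0.149) and a peroxisomal E3 ubiquitin ligase (contig07260, log2 1.45, adjusted p = 0.185). With the slide as a block 8 probes passed, among them contig10269 and contig08140, each with an adjusted p of 0.0468. With the scanner software's normalization contig10269 passed as well (adjusted p = 0.0103). Without replicate 1, 5175 probes passed, without replicate 2, 0 passed, and without either array at 26 °C, 1 passed.

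The direct comparison of 28 °C with 26 °C cancels any dye bias common to the arrays. The replication list lay higher at 28 °C by a median of 0.48, with 79 of 100 probes above 0, DNA repair by 0.26 and the algal list by 0.31, while the matrix list lay at -0.07. The adjusted p with the preset correlation was 1.9e-06, 0.0159, 0.0114 and 0.0381 in that order, and 0.73 for all 4 with an estimated correlation. These directions rested on replicate 2 at 28 °C: without it the 4 values were 0.455, 0.782, 0.836 and 0.89, and the medians -0.0373, -0.0202, 0.0607 and 0.0227, so that 3 of them changed sign. Without replicate 1 at 26 °C they were 0.118, 0.12, 0.551 and 0.453, and without replicate 2 at 26 °C DNA repair had 0.0525. DNA repair had 0.0624 and the matrix 0.0672 with the scanner software's normalization. No probe passed with limma, and 121 (0.435%) had an unadjusted p under 0.05, fewer than a calibrated test gives where nothing differs. The main fit left out that each slide held both temperatures. With the slide as a block 0 passed as well. The lack of calls is therefore no evidence that the temperatures were alike. The glutathione S-transferase probe (contig15720) had a difference of -2.07 (SE 0.494) and the E3 ligase (contig07260) one of 1.24, both with an adjusted p of 1. The next smallest p was that of a growth factor receptor-like protein (contig11774, log2 2.12). Without replicate 1 at 28 °C, 858 probes passed. Without replicate 1 and without replicate 2 at 26 °C, 1 and 7 passed.

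The acidification experiment asked how polyps at pH 6.5, 7.0 and 7.5 differed from those at pH 8.0, and the 3 arrays were fitted together. The gene of a tetraspanin (contig13560), a protein of the cell membrane, was at least 44.7-fold lower (lower on 3 of 3 arrays, adjusted p = 0.0232). Its treated channel was not well above background on any of the 3. Also lower were a protein similar to the scavenger receptor DMBT1 (contig10282, log2 -5.14, SE 0.695, adjusted p = 0.0127) and a C-type lectin (contig05518, log2 -4.34, adjusted p = 0.0319), a sugar-binding protein. Genes of phosphoenolpyruvate carboxykinase, the enzyme that commits oxaloacetate to glucose synthesis, rose on 2 contigs (contig08523, log2 2.67, SE 0.46, adjusted p = 0.0262, and contig17452, log2 2.57, adjusted p = 0.0181). Ferritin (contig11643), which stores iron, rose by 0.79 (SE 0.13, adjusted p = 0.0234).

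Several metabolic genes fell below the level that the arrays could measure. The NUFS7 subunit of the NADH-ubiquinone oxidoreductase (contig24231) was at least 5.97-fold lower (adjusted p = 0.00352), a fatty acid-binding protein (contig00456) at least 6.86-fold lower (adjusted p = 0.0078) and the gamma subunit of isocitrate dehydrogenase (contig22280) at least 5.92-fold lower (adjusted p = 0.00746). Another contig described as NUFS7 (contig22759) had log2 ratios of -0.588 at pH 6.5, -5.22 at pH 7.0 and 0.64 at pH 7.5. Cytochrome P450 genes, which oxidise lipids and foreign compounds, went both ways, with a CYP2 gene higher (contig14370, log2 2.79, adjusted p = 0.0354) and a CYP4/19/26 gene lower (contig11142, log2 -1.39, SE 0.114, adjusted p = 0.00239). Glutathione peroxidase (contig25321), an antioxidant enzyme, fell by 1.37 on the log2 scale (adjusted p = 0.0242), and the beta subunit of a shaker-like potassium channel (contig03124) fell by 2.92 (adjusted p = 0.0248). Also higher were a diacylglycerol acyltransferase (contig03432, log2 1.44), a polyadenylate-binding protein (contig13663, log2 1.51), a NEDD4-like ubiquitin ligase (contig01187, log2 0.77) and cytochrome c (contig06940, at least 1.99-fold). Among stress genes of the fixed panel, the HSP70 probe contig06813 had 0.08 (adjusted p = 0.925), HSP90 0.13 (adjusted p = 0.825), calreticulin -0.17 (adjusted p = 0.86) and carbonic anhydrase (contig19432), which interconverts carbon dioxide and bicarbonate, 0.21 (adjusted p = 0.771). The panel gives only the brightest of 9 kept HSP90 probes. Another HSP90 probe (contig00735) had log2 ratios of 0.569 at pH 6.5, 1.59 at pH 7.0 and -4.95 at pH 7.5.

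By gene group, cytosolic ribosomal proteins lay lower: 171 of 197 probes were below 0, with a median of -0.52 (-0.199 under median centring), 3 passed the test, all lower, and 0 passed when adjusted over the list alone. The 60S protein P0 (contig16005) was the example of smallest p (log2 -1.11, adjusted p = 0.0389). The algal list, of which the passing member of smallest p was an S17-like ribosomal protein of mitochondria or chloroplasts (contig09166, at least 1.67-fold lower), had a median of -0.22, with 3 probes lower and 6 when adjusted over the list alone. With camera the adjusted p was 4.3e-09 for the ribosomal list and 0.000915 for the algal list with the preset correlation, and 0.909 and 0.785 with an estimated correlation. Without the pH 6.5 array the algal list had 0.0755. Without the pH 7.0 array the median was -0.19 for the ribosomal list and -0.415 for the algal list. With the scanner software's normalization the median of the algal list was -0.654. Of 110 detoxification probes 1 passed higher and 4 lower (7 and 13 adjusted over the list alone), of 225 lipid metabolism probes 2 higher and 8 lower (3 and 10 adjusted over the list alone), and of 102 antioxidant probes 1 higher and 4 lower by both adjustments.

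In all, 787 probes passed with limma, 342 higher and 445 lower, and 5474 had an unadjusted p under 0.05. Without the pH 6.5 array 113 passed and without the pH 7.0 array 96. With the slide as a block 1441 passed. Block terms, by slide or by replicate number, covered only the heat and combined arrays. In acidification a block therefore changed only the shared spread, and no slide effect was removed from its arrays. Leaving out an array of another experiment, which enters only through the shared spread, gave 342 to 1123, the lowest without an array at 28 °C with pH 7.5 and 343 without one with pH 7.0. With the spread of the 3 acidification arrays alone, 0 passed. The calls of contig05518, contig11643, contig01187, contig13663 and contig16005 ended with the scanner software's own dye normalization, those of contig25321, contig06940 and contig16005 with median centring, and those of contig05518, contig14370, contig03432, contig06940 and contig16005 with the replicate number as a block. With median centring the split was 659 higher and 232 lower. The 3 arrays carried nearly identical control signals, so a deviation of 1 control pool would stand in all 3 ratios.

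Each pH had 1 acidification array, with no replicate. A PAX1/9-like gene (contig08950) had log2 ratios of 8.2 at pH 6.5, 5.21 at pH 7.0 and 1.91 at pH 7.5, the largest of an annotated probe at pH 6.5. At least 2-fold changes numbered 3229 higher and 2768 lower at pH 6.5 (21.6% of probes), 1772 and 2341 at pH 7.0 (14.8%), and 1151 and 1517 at pH 7.5 (9.6%). In all 3 arrays 278 probes were higher and 361 lower. The ribosomal list had a median of -0.25 at pH 6.5, -0.78 at pH 7.0 and -0.18 at pH 7.5, where median centring turned it to 0.46. The replication list had -0.46, 0.12 and -0.05, the last of which turned to 0.23. The treated signal over background was 1.92, 2.5 and 3.38 in the same order.

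**Figure D1:**
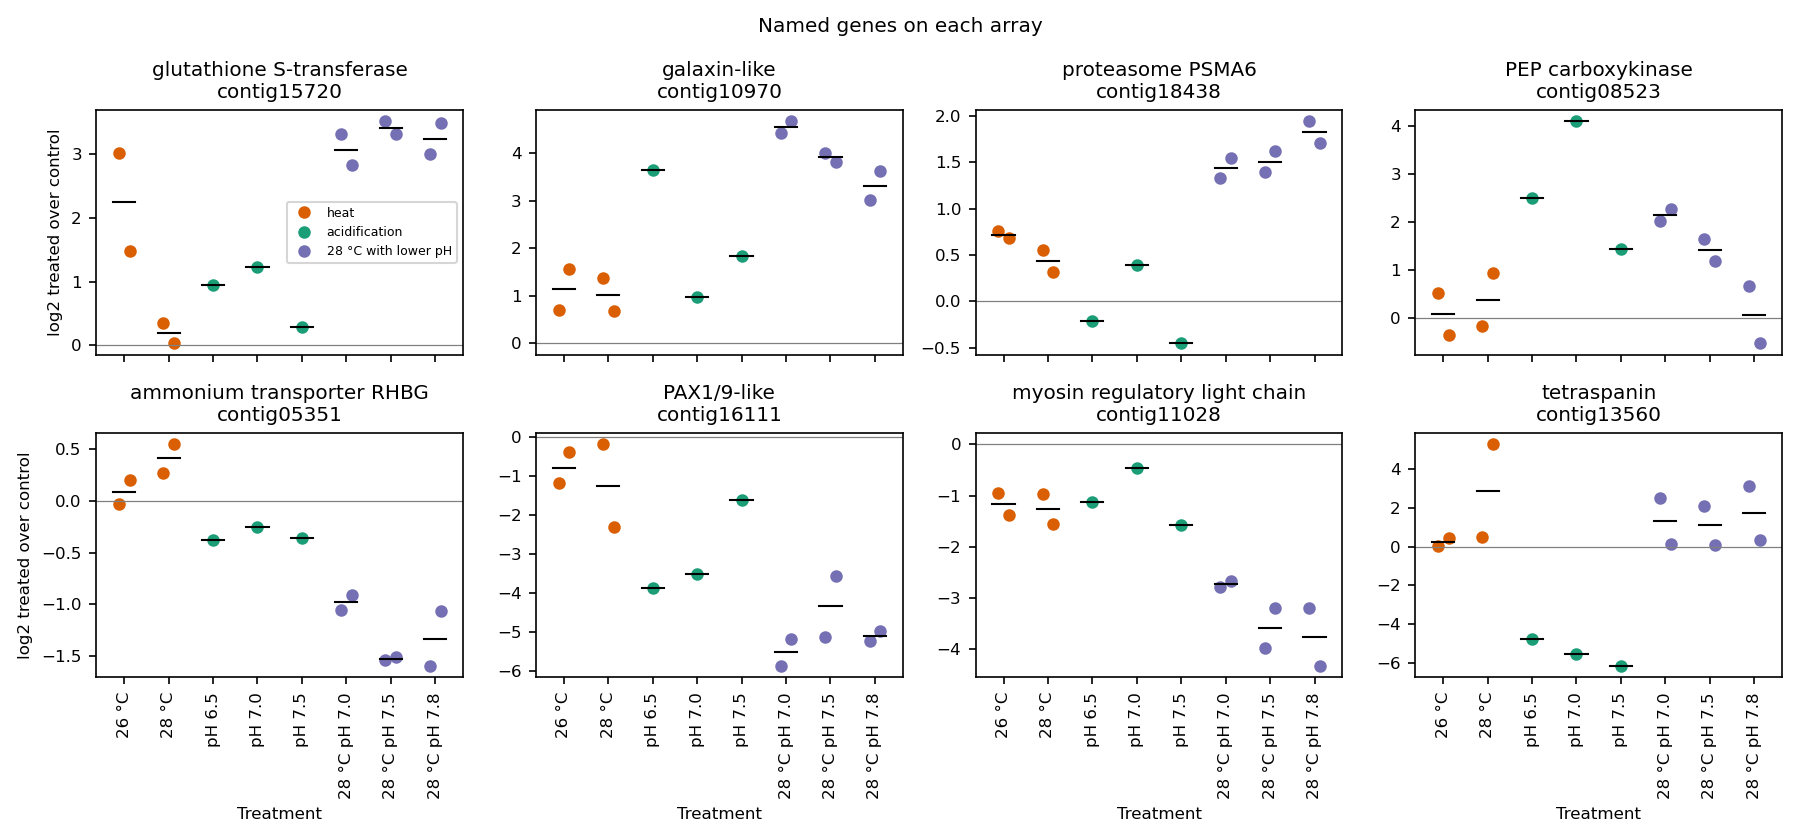
Log2 ratio of treated over control signal (vertical axis) on each array for 8 named genes, by treatment (horizontal axis). Points are arrays, bars the mean of a treatment, and colours the 3 experiments. The ammonium transporter has means of -0.98, -1.53 and -1.33 at 28 °C with pH 7.0, 7.5 and 7.8, and 0.41 at 28 °C alone.

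The combined experiment asked what 28 °C with lower pH did against 24 °C and pH 8.0. At pH 7.0 the genes that rose included a glutathione S-transferase (contig15720), which couples glutathione to toxic compounds, by 3.08 on the log2 scale (SE 0.349, 2 of 2 arrays, adjusted p = 0.00389), a CYP2 cytochrome P450 (contig01334) by 3.47 (adjusted p = 0.00472) and a SAT-1-like sulfate and bicarbonate exchanger (contig00502) by 3.51 (SE 0.454, adjusted p = 0.00501). A gene similar to the skeletal protein galaxin of stony corals (contig10970) rose by 4.55 (SE 0.516, adjusted p = 0.00389). The myosin essential light chain (contig05816) fell by 2.46 (SE 0.265, adjusted p = 0.00333), and so did a phospholipase A2 (contig14097, log2 -3.79, adjusted p = 0.00362) and a lysosomal thiol reductase (contig21169, log2 -2.88, adjusted p = 0.00362). The ammonium transporter RHBG (contig05351), which carries ammonia across membranes, fell by 0.98 on the log2 scale (SE 0.154, adjusted p = 0.00773).

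At pH 7.0 the passing probes of HSP70 and of cytosolic chaperones were higher, and those of endoplasmic reticulum folding lower. For reference, 1788 of all 27793 kept probes rose and 1684 fell. Of 29 HSP70 probes 6 rose and 0 fell (7 and 0 adjusted over the list alone), with contig10940 at 1.5 (adjusted p = 0.00965). HSP90 (contig19522) rose by 1.16 (SE 0.274, adjusted p = 0.0277). Of 84 probes of other heat shock proteins 6 rose, which is near the share over all probes, and 0 fell. A DnaJ protein (contig03130) was at 0.80 (adjusted p = 0.00734). Of 355 probes of the proteasome and ubiquitin system 42 rose and 10 fell, in both cases the same counts when adjusted over the list alone. Of 55 probes of endoplasmic reticulum folding 0 rose and 6 fell, with a protein disulfide isomerase (contig29939) at -1.98 (adjusted p = 0.00722, and a ratio of -0.58 that no longer passed under median centring). The median of that list was 0.04 and its mean -0.26. Of 211 actin, tubulin and muscle probes 9 rose and 28 fell (12 and 32 adjusted over the list alone), and of 232 matrix probes 18 rose and 33 fell (24 and 51). Catalase (contig11069), which breaks down hydrogen peroxide, fell by 1.19 (SE 0.297, adjusted p = 0.0333), but its ratio was 0.0536 under median centring. The calls of contig03130 and contig11069 ended with the scanner software's normalization. With camera, the adjusted p with the preset correlation was 0.0221 for HSP70 (median 0.27) and for the proteasome (median 0.14), and 0.0366 for ribosomal proteins (median -0.17, which turned to 0.65 under median centring). It was 0.748, 0.748 and 0.807 with an estimated correlation. Under median centring HSP70 had a median of 0.675 and the proteasome one of 0.24. Without replicate 1 HSP70 had 0.101, and without replicate 2 the ribosomal list had 0.16. The ribosomal list had 0.0875 with the replicate number as a block and 0.1 with the scanner software's normalization.

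Some of the largest changes at pH 7.0 were those of descriptions shared by many contigs. A PAX1/9-like gene (contig08950) was higher by 7.28 (SE 1.57) and another (contig16111) was at -5.51 (SE 0.635). An Sm-like gene (contig09889) was at 6.15 and a second one (contig18048) at -4.72. A ficolin-like protein (contig23748) was at 4.97, a MafK-like bZIP factor (contig04789) at 4.33, a neurexin IV-like gene (contig18766) at -5.51 and subunit 4 of NADH dehydrogenase (contig00560) at -5.53. In all 3472 probes passed with limma, 1788 higher and 1684 lower, and 7556 had an unadjusted p under 0.05. Of 336 contigs with 2 kept probes, 76 had a passing probe, and on 69 of these the other probe had the same direction, while both passed on 19. In acidification 11 contigs had a passing probe, with the same direction on 8 and both passing on 0. The counts were 8, 8 and 3 at 28 °C with pH 7.5 and 5, 5 and 1 with pH 7.8. With median centring the split was 2339 and 775. Without replicate 1 37 probes passed and without replicate 2 86.

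At 28 °C with pH 7.5, the same glutathione S-transferase probe (contig15720) rose by 3.42 (SE 0.349, 2 of 2 arrays, adjusted p = 0.00544), galaxin (contig10970) by 3.92 (adjusted p = 0.0124) and the PSMA6 subunit of the 20S proteasome (contig18438) by 1.51 (SE 0.197, adjusted p = 0.0121). Troponin T (contig33377), a muscle protein, was at least 5.78-fold higher (adjusted p = 0.00571), while the myosin regulatory light chain (contig11028) fell by 3.59 (SE 0.339, adjusted p = 0.00428). A short-chain dehydrogenase-like gene (contig19468) fell by 3.59 (SE 0.207, adjusted p = 0.000484). The ammonium transporter (contig05351) fell by 1.53 (SE 0.154, adjusted p = 0.00544), and subunit E of the proton pump V-ATPase (contig09278) rose by 0.86 (adjusted p = 0.0261). A TNF receptor-associated factor (contig04312), of a family that relays immune signals, fell by 2.12 (adjusted p = 0.00428).

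By gene group at pH 7.5, HSP70 probes had a median of 0.41, with 24 of 29 above 0. Of these 0 passed over all probes, and 8 rose when adjusted over the list alone. Of 232 matrix probes 2 rose and 12 fell (5 and 24 adjusted over the list alone), of 211 actin, tubulin and muscle probes 1 rose and 6 fell, and of 165 innate immunity probes 0 rose and 6 fell. With camera the adjusted p with the preset correlation was 2.2e-06 for HSP70, 0.000683 for the respiratory chain (median 0.24), the other heat shock proteins (0.20), the proteasome (0.15) and translation (0.15), 0.00962 for ribosomal proteins (0.27) and 0.0193 for endoplasmic reticulum folding (0.13), all upward. With an estimated correlation it was 0.188, 0.257, 0.3, 0.188, 0.4, 0.875 and 0.316 in that order. Under median centring the 7 medians were 1, 0.74, 0.72, 0.61, 0.70, 1.46 and 0.49. With the replicate number as a block as well as an estimated correlation, HSP70 and the proteasome had 0.0374. Without replicate 1 the preset value was 0.331 for ribosomal proteins (median 0.0602) and 0.0652 for endoplasmic reticulum folding, the other heat shock proteins and translation. In all 740 probes passed, 158 higher and 582 lower, and 4975 had an unadjusted p under 0.05. The slide as a block gave 1375, without replicate 1 3 and without replicate 2 4, and without an array of another treatment 321 (28 °C with pH 7.0) to 1132 (28 °C). With median centring 2574 were higher and 343 lower. The calls of contig09278 and of the PAX1/9-like contig16111 (log2 -4.33) ended with the scanner software's normalization.

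At 28 °C with pH 7.8, the mildest acidification, the glutathione S-transferase (contig15720) rose by 3.24 (SE 0.349, 2 of 2 arrays, adjusted p = 0.00673), galaxin (contig10970) by 3.32 (adjusted p = 0.024) and PSMA6 (contig18438) by 1.83 (SE 0.197, adjusted p = 0.00673). Troponin T (contig33377) was at least 5.75-fold higher (adjusted p = 0.00673), and the myosin regulatory light chain (contig11028) fell by 3.76 (SE 0.339, adjusted p = 0.00384). The ammonium transporter (contig05351) fell by 1.33 (SE 0.154, adjusted p = 0.00767) and the TNF receptor-associated factor (contig04312) by 1.84 (adjusted p = 0.00628). A flavin-containing monooxygenase (contig02490), a detoxifying enzyme, rose by 2.11 (adjusted p = 0.0226), and an HSP70 gene (contig30608) by 1.39 (SE 0.22, adjusted p = 0.0248). Calreticulin (contig02102) had 1.68 (SE 0.448, adjusted p = 0.0997) and carbonic anhydrase (contig19432) 1.16 (adjusted p = 0.144, and 0.0271 with the slide as a block). The arrays at pH 7.0, pH 7.5 and pH 7.8 shared slides. Their control channels correlated by 0.9979 to 0.9981 on the slide of replicate 1 and by 0.9969 to 0.9981 on that of replicate 2. A deviation of a control pool would therefore stand in the ratios of all these treatments, and genes that recur between them are not independent evidence.

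HSP70 probes had a median of 0.48 at pH 7.8, with 26 of 29 above 0. Of these 1 rose over all probes and 9 when adjusted over the list alone, and 0 fell in either case. Of 232 matrix probes 2 rose and 8 fell (5 and 20 adjusted over the list alone). With camera the adjusted p with the preset correlation was 1.8e-07 for HSP70, 1.11e-06 for translation (median 0.20), 5.43e-06 for the other heat shock proteins (0.28), 3.7e-05 for ribosomal proteins (0.43), 0.000104 for the respiratory chain (0.24), 0.000164 for the proteasome (0.18) and 0.000721 for endoplasmic reticulum folding (0.26), all upward. It was 0.0439 for neuronal markers (-0.14) and for the matrix (-0.13, which turned to 0.03 under median centring). With an estimated correlation it was 0.116, 0.244, 0.116, 0.673, 0.116, 0.116, 0.116, 0.449 and 0.562 in that order. Under median centring the first 7 medians were 0.84, 0.83, 0.82, 1.72, 0.84, 0.60 and 0.48, and that of neuronal markers was -0.07. With the replicate number as a block as well, HSP70 and the proteasome had 0.0276. The neuronal call ended without either array (0.104 and 0.115) and the matrix call without replicate 1 (0.229), and with the slide as a block these lists had 0.0571 and 0.051. Without replicate 1 the medians of ribosomal proteins, the respiratory chain and translation were 0.292, 0.272 and 0.124. Without replicate 2 they were 0.255, 0.14 and 0.233. In all 509 probes passed, 107 higher and 402 lower, and 4599 had an unadjusted p under 0.05. The slide as a block gave 1110, with the replicate number as a block 832, without replicate 1 51 and without replicate 2 61, and without an array of another treatment 211 (28 °C with pH 7.0), 231 (with pH 7.5) or up to 824 (28 °C). With median centring 3092 were higher and 320 lower. The calls of contig05351 and of contig16111 (log2 -5.1) ended with the scanner software's normalization.

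What lower pH added at 28 °C was tested as the mean of the combined treatments minus 28 °C alone. The ammonium transporter (contig05351) fell by 1.69 on the log2 scale (SE 0.178, adjusted p = 0.0258), with means of -0.98, -1.53 and -1.33 in the combined treatments against 0.41 at 28 °C. The dehydrogenase-like gene (contig19468) had a difference of -2.63 (SE 0.239, adjusted p = 0.0127) and a steroid reductase (contig09617) one of -1.63 (SE 0.198, adjusted p = 0.044). These were the 3 annotated probes among 13 that passed, 1 higher and 12 lower, while 4349 had an unadjusted p under 0.05. HSP70 contig06813 had a difference of -0.47 (adjusted p = 0.554) and catalase one of -0.88 (adjusted p = 0.284). The replication list lay lower by a median of -0.63, DNA repair by -0.40 and the algal list by -0.19, and translation lay higher by 0.10. The adjusted p with camera was 2.76e-05 for replication and 0.034 for the other 3 with the preset correlation, and 0.673 for all 4 with an estimated correlation. The sizes rested on replicate 2 at 28 °C: without it the values were 0.627, 0.935, 0.561 and 0.566, and the medians -0.0558, 0.0263, -0.0818 and 0.0586, with the sign changed for DNA repair. The medians were -1.23, -0.745, -0.475 and 0.22 without replicate 1 at 28 °C. Without replicate 1 at pH 7.0 DNA repair had 0.0605, the algal list 0.0671 and translation 0.0785, without replicate 1 at pH 7.8 they had 0.0971, 0.0971 and 0.122, and without replicate 1 at pH 7.5 translation had 0.108. DNA repair and the algal list had 0.0833 with the scanner software's normalization, under which the 4 medians were -0.998, -0.497, -0.487 and 0.387. Under median centring they were -0.734, -0.486, -0.32 and 0.158, and with scaling between arrays -0.436, -0.214, -0.209 and 0.0393.

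With the slide as a block 144 probes passed in this comparison, and with the replicate number as a block 68. Without replicate 1 at 28 °C 4281 passed and without replicate 2 3. Without replicate 1 at pH 7.5 3 passed, without replicate 2 at pH 7.8 4, without replicate 1 at pH 7.0 6, and without replicate 2 at pH 7.0, replicate 2 at pH 7.5 or the acidification array at pH 7.5 7. Without the acidification array at pH 6.5 24 passed. All 3 annotated calls ended with the scanner software's normalization, those of contig05351 and contig09617 with median centring, and that of contig09617 with the replicate number as a block. The 2 experiments lay on separate slides, and whether they shared a control pool is not stated, so experiment and treatment cannot be told apart. The 6 combined arrays lay on 2 slides, and control channels within a slide correlated by 0.9969 to 0.9981. The fit treated these arrays as independent, so its standard errors and calls do not fully allow for a deviation shared by a slide.

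The dose within the combined experiment was tested as the change per unit fall of pH between pH 7.8 and pH 7.0. Ribosomal proteins lay lower with falling pH: 164 of 197 probes were below 0, with a median of -0.60 per unit. The treated signal was 1.98 and 2 times the background at pH 7.0, against 2.66 to 3.19 times at pH 7.5 and 7.8, and its part in the dose values was not tested. Endoplasmic reticulum folding had a median of -0.26, the respiratory chain -0.21, lipid metabolism -0.20, translation -0.19, replication -0.24 and the other heat shock proteins -0.13, and 18 probes of transposable element proteins had 0.24. With camera and the preset correlation the adjusted p was 2.07e-12, 5.52e-07, 0.00373, 0.0162, 0.000629, 0.018, 0.0499 and 0.018 in that order. With an estimated correlation it was 0.573, 0.0852, 0.436, 0.339, 0.573, 0.749, 0.618 and 0.573. Under median centring the medians per unit were -0.965, -0.77, -0.56, -0.60, -0.535, -0.71, -0.42 and 0.45. Leaving out 1 combined array in turn gave medians of -0.246 to -0.422 for endoplasmic reticulum folding. They were -0.0896 to -0.354 for translation and -0.0776 to -0.415 for replication. Without replicate 2 at pH 7.0 the preset value was 0.0509 for lipid metabolism, 0.06 for translation, 0.212 for transposable elements and 0.352 for the other heat shock proteins. Without replicate 1 at pH 7.8 it was 0.161 for translation, 0.133 for transposable elements and 0.325 for the other heat shock proteins. Replication had 0.0796 without replicate 1 at pH 7.0 and 0.305 without replicate 2 at pH 7.8, and the other heat shock proteins had 0.108 without replicate 1 at pH 7.5. With the scanner software's normalization the other heat shock proteins had 0.169, with the replicate number as a block 0.0703 and with the slide as a block 0.0693.

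No single probe passed for the dose with limma, and 2514 had an unadjusted p under 0.05. The slide as a block gave 2, and leaving out 1 array gave up to 6: 6 and 4 without replicate 2 and 1 at pH 7.8, 3 and 2 without replicate 2 and 1 at pH 7.0, and 1 without the acidification array at pH 6.5. Calreticulin (contig02102) had -1.99 per unit (SE 0.783, adjusted p = 0.508), carbonic anhydrase (contig19432) -1.63 (adjusted p = 0.508) and HSP90 (contig19522) 0.67 (adjusted p = 0.733). The annotated probes of smallest p were that of a probe whose best match names no gene (contig12981, log2 5.89, adjusted p = 0.0725), a signal peptidase I (contig17569, log2 -1.46, adjusted p = 0.172) and an OCT-1-like factor (contig01819, log2 1.84, adjusted p = 0.204).

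**Figure D2:**
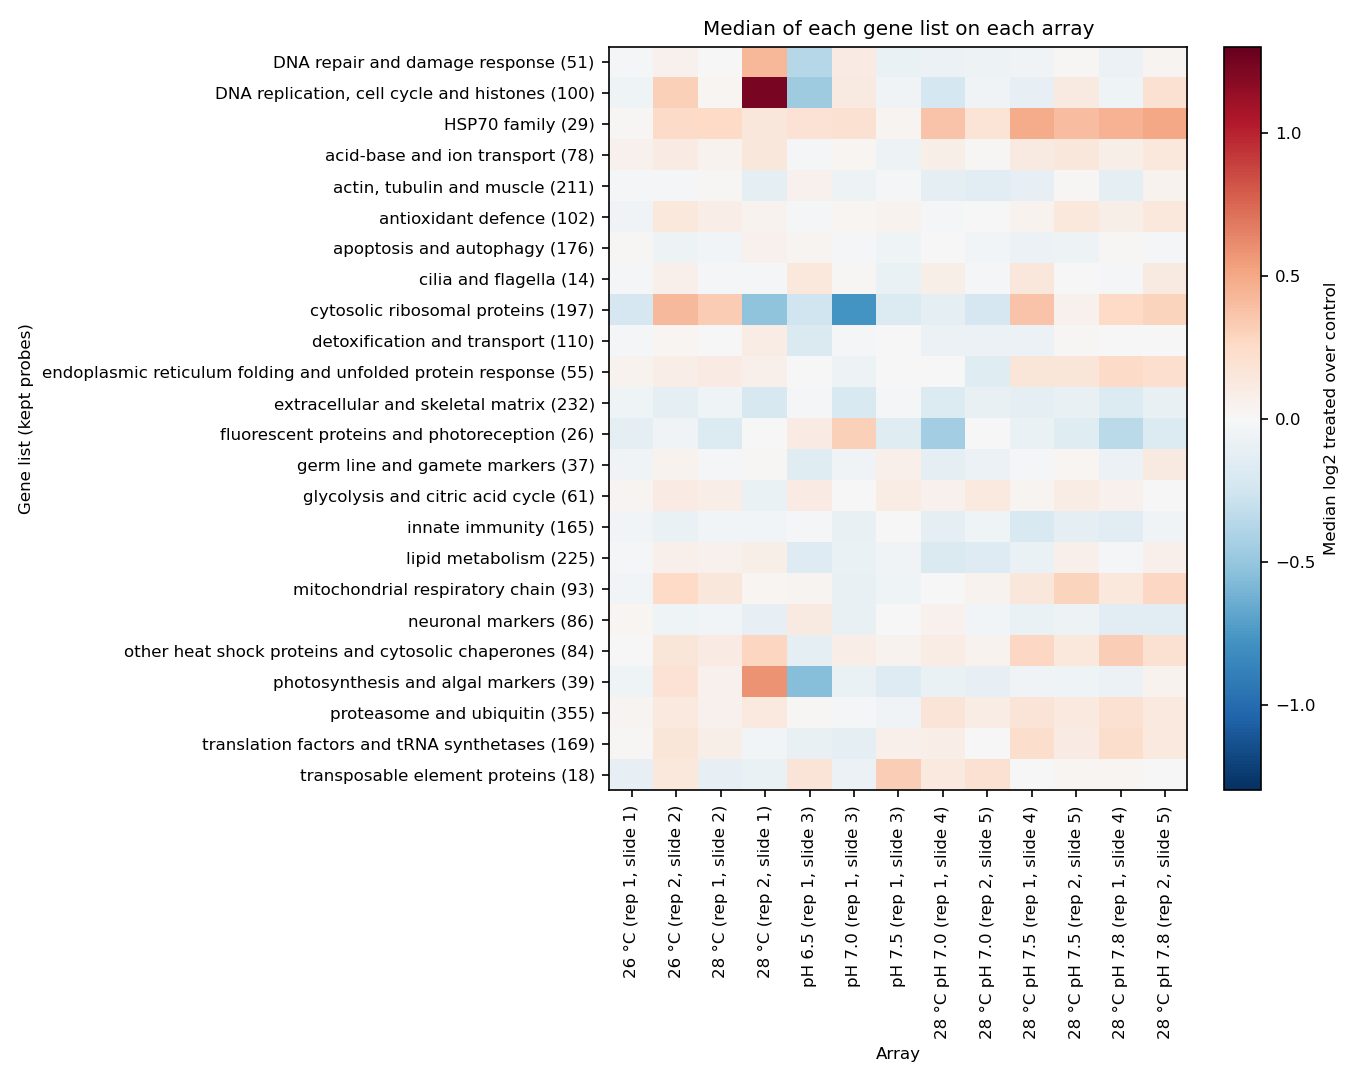
Median log2 ratio of treated over control (colour) of each gene list (vertical axis, with its number of kept probes) on each array (horizontal axis). The HSP70 list lies between 0.17 and 0.51 on the 6 combined-stress arrays, and the replication list reaches 1.23 on 1 array at 28 °C.

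Lists that passed in no comparison with either correlation were acid-base and ion transport, antioxidant defence, apoptosis and autophagy, cilia and flagella, detoxification and transport, fluorescent proteins and photoreception, germ line and gamete markers, and innate immunity. At 26 °C the fluorescent protein list (median -0.26, adjusted p = 0.0525) had 0.0096 with the replicate number as a block. The acid-base list had 0.0381 at 28 °C with pH 7.5 and 0.0332 with pH 7.8 by the scanner software's normalization. Of the 51 list calls with the preset correlation over all comparisons, the median was more than 2 times as large for 28 under median centring and for 24 with the scanner software's normalization, and it changed sign for 3 and 0. The stinging cell list, with 1 kept probe, and the list of early response transcription factors, with 2, were too small for the test. Of 78 acid-base probes 5 rose and 3 fell at 28 °C with pH 7.0, 2 rose and 2 fell at pH 7.5, and 1 rose and 3 fell at pH 7.8. Over all 27793 kept probes 1788 rose and 1684 fell at pH 7.0. Of 176 apoptosis probes 16 rose and 7 fell at pH 7.0. Of 102 antioxidant probes 11 rose and 3 fell at pH 7.0. Of 37 germ line probes 1 rose and 1 fell at pH 7.0, a Piwi-like gene (contig07465) being higher by 0.77 (adjusted p = 0.033). Of 26 probes of fluorescent proteins and photoreception 1 rose and 1 fell, the latter similar to a green fluorescent protein (contig10286, log2 -2.59, adjusted p = 0.0472). None of 14 cilia probes passed in the acidification or combined comparisons.

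Across probes, which are not independent replicates, replicate arrays at one temperature had a Pearson correlation of 0.0404 at 26 °C and -0.083 at 28 °C, while the heat arrays that shared a slide had 0.37 and 0.658. Replicates of the combined treatments had 0.773 at pH 7.0, 0.586 at pH 7.5 and 0.414 at pH 7.8. Combined arrays of different pH on one slide had 0.707 to 0.804 for replicate 1 and 0.427 to 0.9 for replicate 2. Arrays at pH 7.5 and pH 7.8 on one slide had 0.772 and 0.9, more than the replicates of either treatment. The control channels of arrays on one slide had correlations of 0.9942 to 0.9983, and those on different slides 0.8475 to 0.9689.

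**Figure D3:**
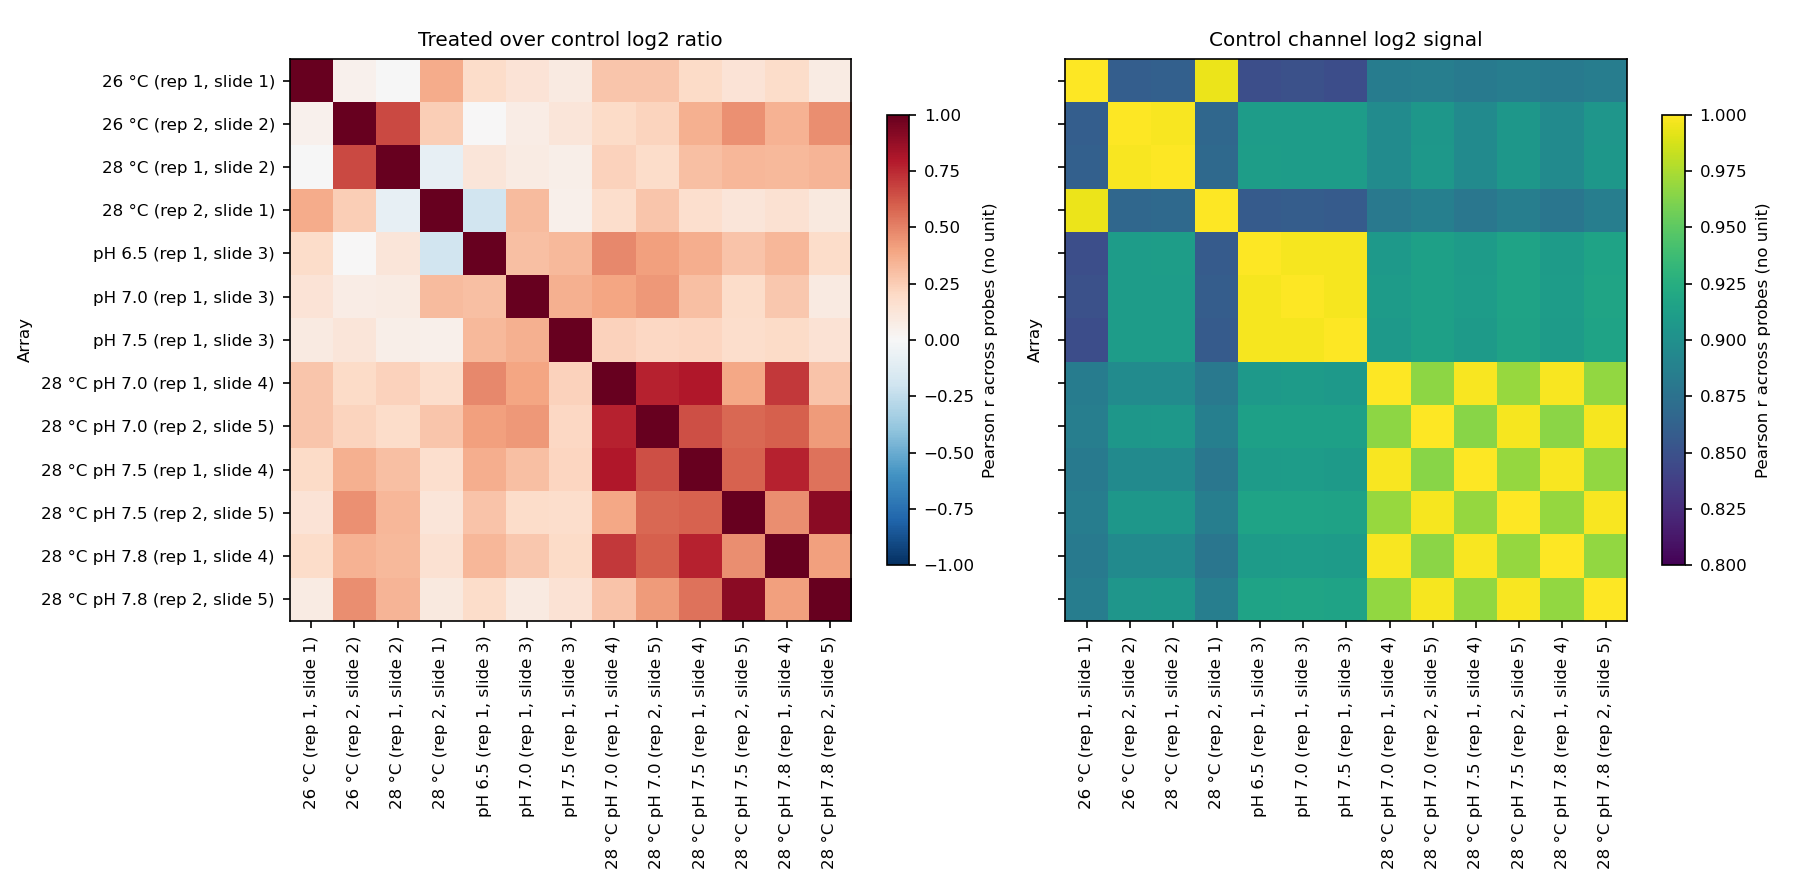
Pearson correlation across probes (colour) between all pairs of the 13 arrays (both axes), of the log2 ratios on the left and of the control channel on the right. Control channels of one slide correlate at 0.9942 or more, and those of different slides at 0.9689 or less.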

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

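All tests of explanations here and under other observations were chosen, and their bounds set, after the patterns had been seen.

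The heat arrays agreed by slide and not by temperature, and 59 probes differed between the slides of the heat experiment by limma, 34 higher and 25 lower on the second. Arrays of a slide appear to carry 1 control RNA, since their control channels were nearly identical. The covariance of the 2 heat ratios on a slide was 0.327 and 0.119, against a variance of 0.444 estimated from the difference of the control channels. The larger is 0.736 of it. That difference also holds any slide effect common to both dyes, which cancels in a ratio. The variance of the difference between slides was 0.864 to 0.913 for the control channels and 0.91 to 1.53 for the treated ones. The 0.444 may therefore exceed what a control pool adds. A shared control is a candidate explanation, but these values cannot show that it is large enough, and data found from the pattern cannot settle it. An exchange of the 26 °C and 28 °C labels on 1 slide would pair arrays that correlate by -0.0037 and 0.248, against 0.0404 and -0.083 for the pairs as labelled. Pairs of one temperature correlate little with either labelling, so the 2 cannot be told apart by these values. No biological explanation was tested, since each slide held both temperatures.

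The replicates of the combined treatments also differed by slide, with 16 probes past the threshold, 4 higher and 12 lower on the slide of replicate 2. The covariance of the replicate differences between pH levels was 0.259 to 0.475, against a variance of 0.218 for the difference between the control channels. The ratio was 1.19 to 2.17, so a control that differed may account for part of it, and what else is shared stays open. A longer exposure, 48 h in the table titles of that slide, cannot be told apart from the slide, because every array with that title lay on it, and the 16 probes decide nothing between them. Of the 2 annotated probes, one (contig03510, RANBP3-like) had a difference of -5.52 and the other (contig18201, similar to SVEP1) one of 4.46.

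The combined treatments differed from 28 °C alone at 13 probes by a test of the difference itself. Gene lists differed between treatments with camera's preset correlation, with 1 probe per description and with the scanner software's normalization but none with an estimated correlation, and several calls ended when 1 array was left out. The lists were the replication list (median 0.478) and the algal list (0.31) at 28 °C against 26 °C, and the replication list in the combined treatments against 28 °C (-0.627). Without replicate 2 at 28 °C the adjusted p of these 3 was 0.455, 0.836 and 0.627, and without replicate 1 at 26 °C that of the first pair was 0.118 and 0.551. For the change per unit fall of pH they were ribosomal proteins (-0.6), replication (-0.236), endoplasmic reticulum folding (-0.256), lipid metabolism (-0.203), the respiratory chain (-0.209) and translation (-0.188). Leaving out 1 array gave adjusted p of up to 0.305 for replication, 0.0509 for lipid metabolism and 0.161 for translation, and the other 3 stayed past the threshold. Between the heat slides, ribosomal proteins differed by a median of 0.76 (adjusted p = 1.59e-17 with the preset correlation and 0.746 with an estimated one), fluorescent proteins by -0.822 (0.0189 and 0.746) and translation by 0.142 (0.0149 and 0.823). Between the slides of the combined experiment, translation differed by -0.124 (0.0128 and 0.625).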

How the results depend on the processing

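Of the alternatives below, 4 kinds were chosen after seeing the data: the combined-stress arrays of 1 slide only, crossed heat numbers as a block, the filter on all 13 arrays in acidification, and the slide as a block for gene lists. For the changes that follow, the cause was not tested, except where arrays or probes were left out and fewer remained.

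With the scanner software's normalization, 1 probe passed at 26 °C, 1 at 28 °C and 1 for the pH dose, where 0 had passed, 278 passed at 28 °C with pH 7.8, and 2 passed for the combined treatments against 28 °C. On the single acidification arrays it gave 13044, 9386 and 6413 changes of at least 2-fold at pH 6.5, 7.0 and 7.5. With the matrix values, 1 probe passed at 26 °C, 2 at 28 °C, 295 at pH 7.8, 7 for the combined treatments against 28 °C and 1 for the dose.

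With median centring, 2917 probes passed at 28 °C with pH 7.5, 3412 with pH 7.8 and 73 for the combined treatments against 28 °C, and the acidification array at pH 7.5 had 4492 changes of at least 2-fold. Most of the added calls were higher, as the splits of 2574 to 343 and 3092 to 320 show. Calls that changed sign were contig07766, a 40S ribosomal protein SA (0.749), and catalase contig11069 (0.0536) at pH 7.0, the ubiquitin hydrolase contig06972 at pH 7.5 (0.344) and pH 7.8 (0.485), and the disulfide isomerase contig29939 at pH 7.8 (0.0478). With scaling between arrays, 6 probes passed at 26 °C, 5 at 28 °C and 1 for the dose.

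With array weights, 7460 passed at 28 °C with pH 7.0, 3567 with pH 7.5, 850 with pH 7.8, 2 for the combined treatments against 28 °C and 10 for the dose. With the arrays of the comparison alone, 0 passed in acidification, where 787 had passed, 1214 at pH 7.5, 1079 at pH 7.8 and 2 for the combined treatments against 28 °C. Without a filter, 2 passed for the dose. With probes well above background in both channels, and likewise with the authors' reliable probes, 2 passed for the combined treatments against 28 °C.

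With the replicate number as a block (replicate block), 832 probes passed at pH 7.8 and 68 for the combined treatments against 28 °C. The other counts of single probes stayed within 1.5 times: 0 in the heat comparisons and for the dose, 849 in acidification, 3936 at pH 7.0 and 1098 at pH 7.5. With the slide as a block 8 passed at 28 °C, 1441 in acidification, 1375 at pH 7.5, 1110 at pH 7.8, 144 for the combined treatments against 28 °C and 2 for the dose. Acidification had no block term of its own under either block, so its counts moved only through the shared spread. The crossed heat numbers as a block are the same blocks as the slides and gave the same counts: 8, 1441, 1375, 1110, 144 and 2.

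With the combined-stress arrays of replicate 1 only, whose tables are titled 24 h, 67 passed in acidification, 84 at pH 7.0, 22 at pH 7.5, 27 at pH 7.8 and 1 for the dose. With those of replicate 2 only, titled 48 h, 67, 13, 15 and 29 passed in the first 4 of these. With only probes well above background on all 13 arrays, 573 passed in acidification.

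Leaving out each array in turn gave 0 to 11 probes at 26 °C, 0 to 5175 at 28 °C, 0 to 858 for 28 °C against 26 °C, 96 to 1123 in acidification, 37 to 4228 at pH 7.0, 3 to 1132 at pH 7.5, 51 to 824 at pH 7.8, 3 to 4281 for the combined treatments against 28 °C and 0 to 6 for the dose. Where 1 array remained, it was assumed to vary like the other treatments.

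With an estimated correlation, 0 gene lists passed in any of the 9 comparisons, against 5, 9, 4, 2, 3, 7, 9, 4 and 8 with the preset one, in the order of the report. With the replicate block as well, HSP70 and the proteasome passed at pH 7.5 (0.0374) and pH 7.8 (0.0276). With 1 probe per description, 3 lists passed at 26 °C, 0 at pH 7.0 and 2 for the combined treatments against 28 °C. With the scanner software's normalization, 2 passed for 28 °C against 26 °C and 2 for the combined treatments against 28 °C. With the replicate block, 9 passed at 26 °C.

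The values of single named genes include calls and values that had not passed, and only a call could end. The numbers that stayed are therefore not the share of calls kept. With the scanner software's normalization 186 stayed on their side of the threshold, 51 calls ended and 2 were added. With median centring 192 stayed, 28 ended, 14 were added and 5 changed sign. Without background correction 237 stayed and 2 ended, with the replicate block 219 stayed, 19 ended and 1 was added, and with the slide as a block 229, 4 and 6. Leaving out 1 array in turn, over all arrays, 2552 stayed, 545 ended and 10 were added. The counts for leaving out 1 array include arrays outside the comparison, which enter only through the shared spread. Among 1620 values that had not passed, 61 changed sign under an alternative. The median signal over background was 1.92 at its lowest, and a probe that was dim in 1 channel on every array of a group has only a bound on its ratio.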

Other observations

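Acidification alone and 28 °C with pH 7.0 changed many of the same probes in the same direction. Among 377 such probes were a phosphoenolpyruvate carboxykinase (contig17452, log2 2.57 and 2.37), an ARNT-like transcription factor (contig03218, 1.88 and 2.01), an IRP-like aconitase (contig27528, 1.75 and 1.93), which regulates iron use, and a mitochondrial carrier (contig10124, 1.95 and 3.17), all higher. Lower in both were a sterol C5 desaturase (contig04544, -2.58 and -2.95), a 17-beta dehydrogenase 11 (contig05720, -2.78 and -2.43) and an HSD17B3-like enzyme (contig16172, -2.08 and -1.7). These genes were chosen after their values were seen. Few members of the gene lists were shared: 3 higher and 0 lower for the proteasome, 2 and 0 for glycolysis, 0 and 4 for actin, tubulin and muscle, 0 and 3 for neuronal markers, 0 and 2 for detoxification, 0 and 1 for replication, 1 and 1 for the respiratory chain, and 1 and 3 each for the matrix, lipid metabolism and translation. The other lists had 0, and no enrichment was tested. Independent lists would share 49 probes by direction, and 7 were called in opposite directions. With pH 7.5 at 28 °C 126 were shared (11.3 for independent lists) and with pH 7.8 94 (7.76). With the scanner software's normalization 330, 86 and 50 were shared at pH 7.0, 7.5 and 7.8 (50.5, 5.69 and 3.16), and among probes well above background on all arrays 381, 119 and 72 (57.8, 11 and 7.83).

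A probe dye bias may act on single probes, but it is argued against as the whole source of the 377 shared calls. Turned to the direction of the calls, the 377 probes had a median of 0.168 to 0.279 on the heat arrays and 1.07 to 1.74 on the acidification arrays, a ratio of 0.156 between the medians. A dim treated channel at low pH is argued against too: among 15024 probes well above background in both channels on all 13 arrays, the calls shared in direction were 6.59 times the number for independent lists. Both lists used one estimate of the spread per probe, so they are not independent. A shared spread alone would raise calls in opposite directions too, and those numbered 2, against 57.9 for independent lists. The acidification and combined arrays lay on different slides, but whether their controls came from one pool is not stated, so part of the excess may come from shared controls. A response common to lower pH stays a hypothesis.

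Of the 27758 kept probes measured on all 13 arrays, 1308 had the same direction on all of them, heat arrays included. A mean change of at least 2-fold was found for 485 of these. Of the calls, 20.8% in acidification and 21.6% at 28 °C with pH 7.0 were among the 1308. With pH 7.5 the share was 35.5% and with pH 7.8 it was 37.5%. These shares exceeded that over all measured probes, 1308 of 27758. Each call moved alike on all arrays of its own treatment, which by itself raises the share. A probe dye bias would also give the same direction on all arrays, since no dye was swapped. The dye bias test above covered only calls shared by acidification and 28 °C with pH 7.0. The part of such a bias in other calls, as with pH 7.5 and pH 7.8, was not tested.

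The tetraspanin that fell in acidification (contig13560) had log2 ratios of 0.51 and 5.3 in the 2 arrays at 28 °C. Between the slides of the heat experiment, a teneurin-like gene (contig02562) differed by 4.26 and a collagen-like gene (contig07547) by 3.46, both higher on the second slide, and these genes too were chosen after their values were seen.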
